A study of Mus musculus with 14 samples.

How the data were processed

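Bulk RNA sequencing was done on 14 libraries of transformed mouse embryonic fibroblasts, which are fibroblasts from mouse embryos made able to divide without limit. Per the labels, the mouse telomere protein TRF1, encoded by Terf1, was replaced in these cells by the naked mole rat (NMR) protein or by a mutant form of it. The GLAD mutant carried Glu69Lys, Val70Ala and Ala75Thr. The TIN mutant carried Ala105Thr, and the double mutant carried the GLAD and TIN substitutions together. Each mutant was grown at atmospheric oxygen (normoxia) and at 1% oxygen (hypoxia), and wild-type NMR TRF1 at normoxia. Each of these 7 groups had 2 libraries, named A and B. A hypoxia group of wild-type NMR TRF1 was not analysed here. Per the labels' protocols, cells grew in DEM with 10% fetal calf serum, total RNA was extracted with a MicroElute kit, and libraries were made with a TruSeq RNA kit and sequenced on a NovaSeq instrument.

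The deposited values are CPM, read counts scaled to a common total per library, for 52636 Ensembl mouse genes, 52403 of which had a symbol. Per the submitters' processing notes, reads were aligned with STAR to the mouse genome and counted per gene with HTSeq before CPM were computed. The notes name GRCm38.p4 and mm10 and give no program versions, and the strand setting and annotation release were not given in the sources used here. No other normalization, log transformation or batch correction is recorded by the authors for the deposited CPM.

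The values under 200 CPM in each library were whole multiples of a step near 0.04997 CPM, to within 0.010 of a step. The steps fitted a read count multiplied by a factor of 1.33 to 1.68 and rounded up. With that factor 100% of the low values in each library fitted, against 59.6% to 75.1% by chance. Of all values 99.80% to 99.94% fitted in 13 libraries and 84.91% in double-mutant hypoxia library B, where the reads recovered at higher values are less sure. Dividing by the factor gave 11916989 to 15023545 reads per library. One read then corresponded to 0.0665 to 0.0839 CPM, and a count of 0 allowed up to 3 reads, or 0.200 to 0.252 CPM. These floors cover counting error only. The recovery was tested on 3 simulated libraries, in which 100% of the reads were recovered exactly.

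A count-based quasi-likelihood test had been planned. Because the values were CPM, the comparisons were made instead with limma 3.58.1 in R 4.3.3 on log2 values. CPM were scaled by trimmed mean of M values (TMM) factors, with 30% of log ratios and 5% of mean levels trimmed, and 0.5 CPM was added before log2 was taken. Genes with at least 1 CPM in at least 2 libraries were kept, which left 16157 of the 32273 genes above 0 in any library. A model with 7 group means was fitted to the 14 libraries, with 7 residual degrees of freedom, variances moderated along the trend on mean level, and 10.3 prior degrees of freedom. The 16 comparisons were the hypoxia effect in each mutant and on average over the 3 mutants, the 3 differences of that effect between mutants, each mutant against wild type in normoxia, and the mutants against one another in normoxia and in hypoxia. P-values were adjusted by the Benjamini-Hochberg method within each comparison. A gene with adjusted p under 0.05 was called, and errors given after ± on log2 values are standard errors from the model. Levels are TMM-scaled CPM with the standard deviation over 2 libraries.

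There were 25 gene lists. They covered glycolysis, targets of the hypoxia-inducible factor (HIF) outside glycolysis, nuclear oxidative phosphorylation genes, the mitochondrial genome, the tricarboxylic acid cycle, shelterin and telomere maintenance, DNA replication, mitosis, homologous recombination and Fanconi genes, p53 targets, cholesterol synthesis, the integrated stress response, endoplasmic reticulum chaperones, extracellular matrix, interferon response, inflammatory and secretory genes, NRF2-driven oxidative stress genes, ribosomal proteins and replication-dependent histones. Epithelial, endothelial, myeloid, muscle, neural and adipocyte markers were also listed. Lists with at least 5 measured members were tested with camera, a competitive test in limma that sets a list against all other genes. The preset correlation of 0.01 between genes was used, and the same test was repeated with a correlation estimated from the data. The p-values of the lists were adjusted within each comparison. For each list, called members were counted with the adjustment over all genes, and again with p-values adjusted over the list alone.

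The groups, comparisons, lists, rules for naming genes and first set of alternatives were chosen before the data were examined; the limma test on log2 values, its filter and its pseudocount were chosen after the unit of the values was known. The genes named are the most changed genes of each comparison with a mean of at least 5 CPM, the members of each list that changed most, and 12 genes chosen beforehand: Terf1, Vegfa, Car9, Slc2a1, Hk2, Ldha, Pgk1, Pdk1, Bnip3, Cdkn1a, Mdm2 and Gapdh. Gene symbols stand for the Ensembl genes in the deposited table, and gene positions are those of GRCm38. Paralogs with near-identical sequence, such as H2-Q6 with H2-Q7, the Oas genes and the histones, may share reads in a count per gene.

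The alternatives tried were median-of-ratios scaling, CPM without further scaling, no filter beyond a value above 0, a mean of at least 5 CPM, limma-voom on the recovered reads, a term for the library letter, a fit of the compared groups alone, leaving out each library in turn, an estimated correlation between genes, and a minimum fold of 2. Chosen later were pseudocounts of 0.1 and 2 CPM, limma weights per library, and removal of each library's trend on transcript length and GC content. The letters A and B gave no pairing: of 21 correlations between the A minus B differences of 2 groups, 6 were over 0.1, in a range from −0.15 to 0.30 over 11960 genes.

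The test was checked in 5 simulations of 15603 uncorrelated genes, with a coefficient of variation of 5% and known fold changes. For the hypoxia effect in the GLAD mutant it recovered 40.8% of genes changed 1.25-fold, 82.4% at 1.5-fold, 98.8% at 2-fold and 100% at 4-fold, with 6.2 false calls per simulation. For the TIN minus GLAD difference in effect the shares were 10.8%, 56.4%, 89.6% and 99.6%. No list was called in 110 tests of unchanged lists, which left correlation untested. Tables were handled with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 in Python 3.11.15 and with the data.table package, version 1.17.8, in R. Figures were drawn with matplotlib 3.10.9.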

Results

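Gene expression was measured by bulk RNA sequencing in 14 libraries, 2 for each of 7 groups. The GLAD, TIN and GLAD/TIN double mutants of NMR TRF1 had libraries at normoxia and at hypoxia, and wild-type NMR TRF1 at normoxia. The series asks how this telomere protein bears on glycolysis and telomere replication at low oxygen. Recovered depth was 11916989 to 15023545 reads per library, and a gene at 0 could have held up to 0.200 to 0.252 CPM. The labels do not say whether the A and B libraries of a group came from separate cultures. The p-values therefore measure the spread between these libraries, which may be technical. Each mutant may also be a single cell line, so line and substitution cannot be separated. The names of the wild-type libraries hold the word mouse and follow another naming scheme, while their titles and genotype give NMR TRF1. Any batch of those libraries is thus confounded with genotype. Which TRF1 they carried was not checked, so the comparisons against wild type rest on the titles and would have another meaning if the cells held mouse TRF1.

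Terf1, the gene replaced in these cells (ENSMUSG00000025925, GRCm38 chromosome 1, 15805646 to 15844052), was read in every library. In normoxia it stood at 150.1 and 148 CPM in the GLAD libraries A and B, at 181 and 177 CPM in the TIN libraries, at 129 and 137 CPM in the double-mutant libraries and at 106 and 85.9 CPM in the wild-type libraries. In hypoxia the values were 93.6 and 87.9 CPM for GLAD, 113 and 113 CPM for TIN, and 98.1 and 92.2 CPM for the double mutant. A count per gene cannot tell reads of mouse Terf1 from reads of the NMR sequence, so these levels do not check the replacement or the labels. Terf1 fell in hypoxia by 0.62 ± 0.05 on average over the 3 mutants (log2, adjusted p = 5.2e-09), lying lower in all 6 hypoxia libraries than in all 6 normoxia libraries of the mutants.

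**Figure D1:**
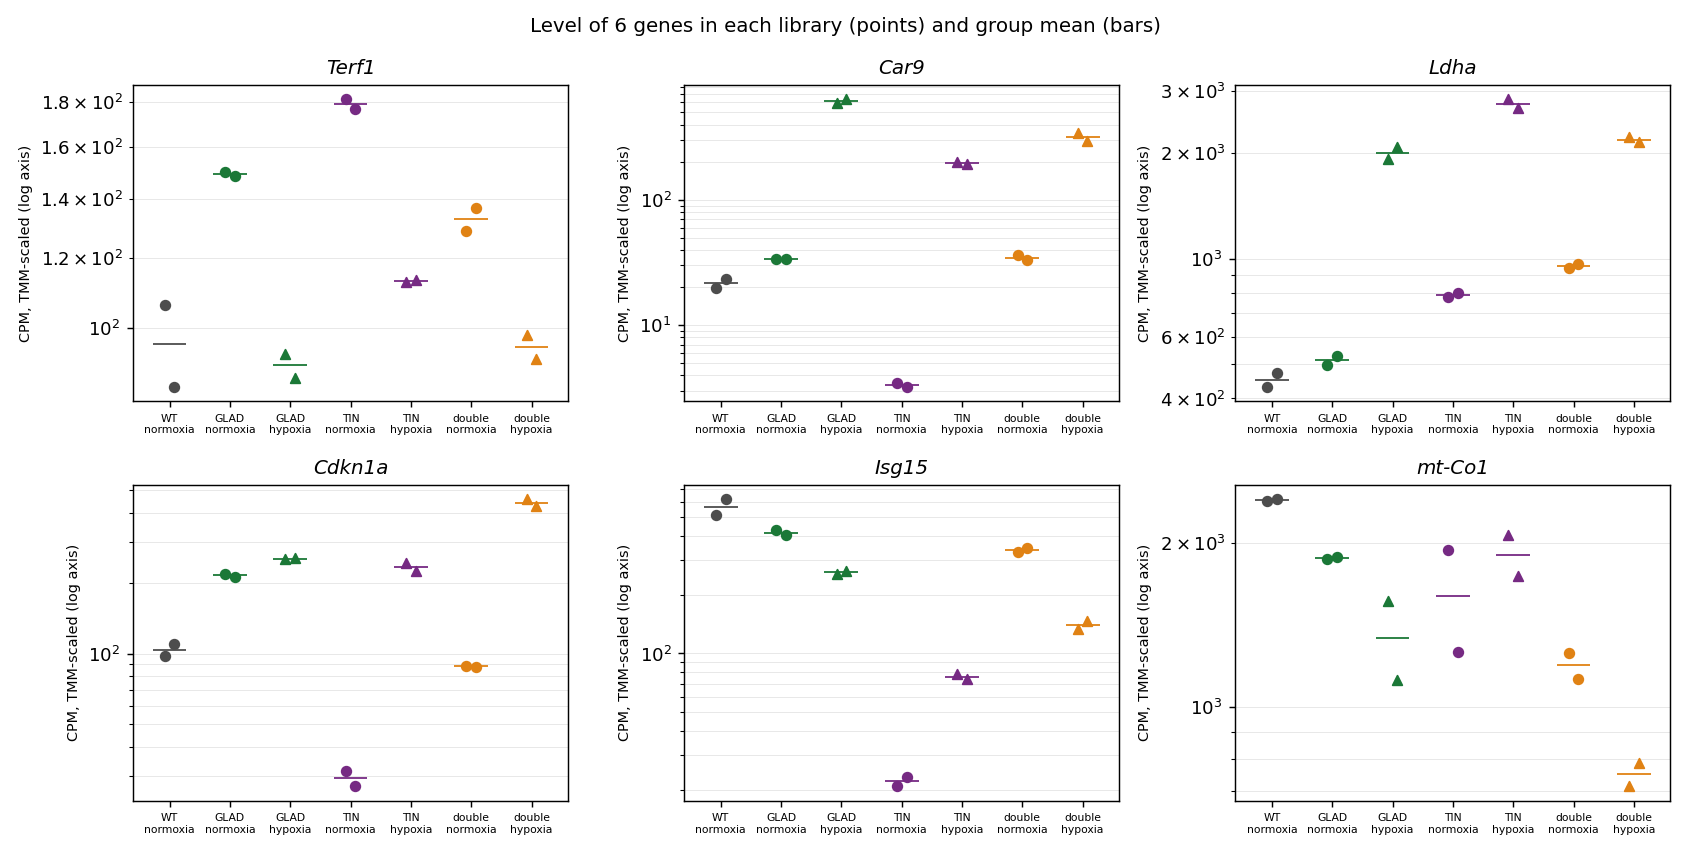
TMM-scaled CPM of 6 genes on log axes in each of the 14 libraries, with circles for normoxia, triangles for hypoxia and bars for the mean of the 2 libraries of a group. Car9 rose in hypoxia from 33.7 to 613 CPM in the GLAD mutant, from 3.35 to 199 CPM in the TIN mutant and from 34.6 to 316 CPM in the double mutant, while Isg15 stood at 22.0 CPM in the TIN mutant and 416 CPM in the GLAD mutant in normoxia.

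The libraries separated by oxygen and by genotype. The first principal component held 31.2% of the variance and ran from the wild-type libraries at −62.7 and −57.1 to the double-mutant hypoxia libraries at 61.5 and 67.9. The second held 30.3% and set the 4 TIN libraries, at 59.4 to 62.8, apart from the other 10, at −37.2 to −13.5. The replicate spread beyond counting error was a biological coefficient of variation of 1.8% to 6.3% in the mutants and 12.6% in the wild type. With little spread the test called many genes, so counts of at least 2-fold changes are given beside each total.

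**Figure D2:**
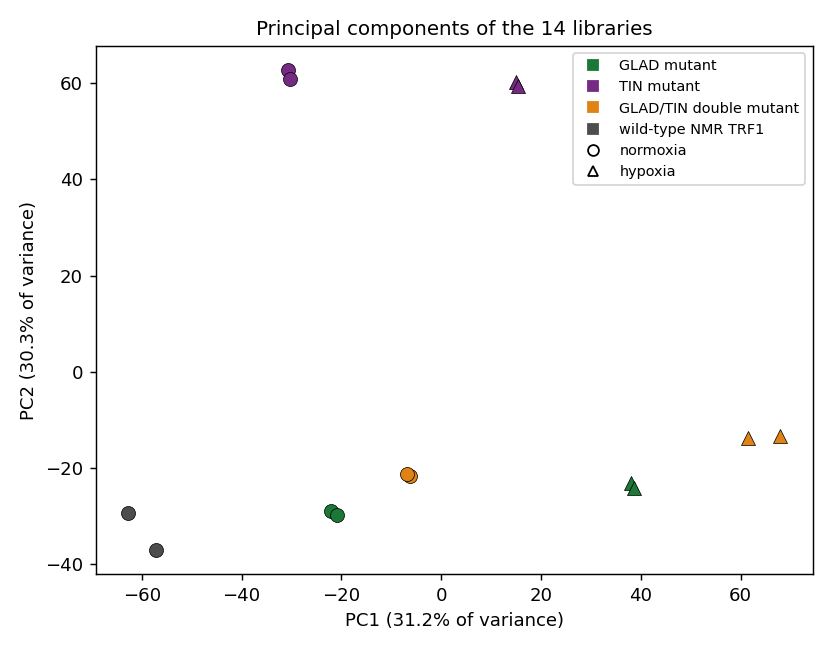
Scores of the 14 libraries on the first 2 principal components of log2 expression, in arbitrary units, with the share of variance on each axis, colours for genotype, circles for normoxia and triangles for hypoxia. The TIN libraries lie at 59.4 to 62.8 on the second component and the other libraries at −37.2 to −13.5.

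The hypoxia effect averaged over the 3 mutants answers how these cells respond to 1% oxygen. The genes of oxygen sensing and of glycolysis rose together. Car9, a carbonic anhydrase that exports acid (ENSMUSG00000028463, GRCm38 chromosome 4, 43506966 to 43513729), rose by 4.34 ± 0.05 (adjusted p = 1.6e-19), the adenylate kinase Ak4 by 3.96 and the mitophagy receptor Bnip3 by 2.96 ± 0.05 (9.2e-19). The angiogenic factor Vegfa rose by 2.54 ± 0.04 (1.2e-18). In glycolysis, the lactate exporter Slc16a3 rose by 2.88 ± 0.08, the pyruvate dehydrogenase kinase Pdk1 by 2.74 ± 0.05 (6.2e-18), the hexokinase Hk2 by 2.57 ± 0.06 (6.8e-17), the glucose transporter Slc2a1 by 2.52 ± 0.04 (2.0e-18), Pgk1 by 1.71 ± 0.04, Ldha by 1.65 ± 0.04 (1.3e-15) and Gapdh by 1.31 ± 0.05. Of the 27 measured HIF targets 27 rose, with 27 when adjusted over the list alone, a median of 2.65 and adjusted p = 6.4e-25 for the list (2.2e-02 with an estimated correlation). Of the 22 glycolysis genes 19 rose and none fell, with the same counts adjusted over the list alone, at a median of 1.55 and adjusted p = 3.8e-14 (adjusted p = 8.2e-02 with an estimated correlation).

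The largest rises of this average were in the receptors Gpr35, by 5.56 ± 0.13, and Gipr, by 5.00 ± 0.11. Aire, known as a thymic regulator, rose by 4.97 ± 0.12, the calcium channel Trpm2 by 4.52 ± 0.16 and the collagen cross-linking enzyme Loxl2 by 3.99 ± 0.06. Gpr35 stood at 0.465 CPM in the GLAD, 0.245 CPM in the TIN and 1.02 CPM in the double mutant in normoxia, close to the floor of 3 reads. Its fold therefore depends on the pseudocount. The largest falls were in the aldo-keto reductase Akr1c14, by 2.06 ± 0.11, the chromatin factor Jade2, by 2.05 ± 0.07, the circadian factor Dbp, by 1.87, and Pif1, by 1.66 ± 0.08 (2.6e-12). Pif1 encodes a helicase that removes telomerase from chromosome ends.

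Mitochondrial genes fell with hypoxia on average. Of 53 nuclear oxidative phosphorylation genes none rose and 40 fell (40 adjusted over the list alone), at a median of −0.24 and adjusted p = 1.3e-05 (adjusted p = 5.4e-01 with an estimated correlation). Atp5g1 fell by 0.81 ± 0.07 and Ndufa4, which HIF replaces by another subunit, by 0.79 ± 0.07. Of 12 mitochondrially encoded genes 9 fell (9 adjusted over the list alone), at a median of −0.68 and adjusted p = 8.0e-03 (5.4e-01 with an estimated correlation), with mt-Cytb down by 1.29 ± 0.10 and mt-Nd4 by 1.12 ± 0.12. Of 18 tricarboxylic acid cycle genes 15 fell and 2 rose (15 and 2 adjusted over the list alone), at a median of −0.27 and adjusted p = 1.2e-03 (1.1e-01 with an estimated correlation). Among them the pyruvate dehydrogenase subunit Dlat fell by 1.02 ± 0.05 and citrate synthase Cs by 0.72 ± 0.04.

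Telomere genes went in mixed directions on average. Of 24 measured shelterin and telomere maintenance genes 9 rose and 9 fell (9 and 9 adjusted over the list alone), at a median of 0.00 and adjusted p = 8.0e-01 for the list (7.9e-01 with an estimated correlation). The telomerase component Dkc1 fell by 0.78 ± 0.05 (2.1e-10), while the helicase Blm rose by 0.68 ± 0.05 (4.1e-09) and the shelterin subunit Tinf2 by 0.57 ± 0.05 (4.3e-08). Of 40 DNA replication genes 28 rose and 5 fell (28 and 5 adjusted over the list alone), at a median of 0.35 and adjusted p = 8.7e-06 (1.1e-01 with an estimated correlation). Cdc6, which licenses origins, rose by 0.98 ± 0.05, Fen1 by 0.79 and Cdc45 by 0.77. Of 31 homologous recombination and Fanconi genes 19 rose and 3 fell (19 and 3 adjusted over the list alone), at a median of 0.19 and adjusted p = 2.8e-03 (2.1e-01 with an estimated correlation). Rad51ap1 rose by 0.95 ± 0.04 and Rad51c fell by 0.63. Of 35 mitosis genes 9 rose and 16 fell (9 and 16 adjusted over the list alone), at a median of −0.09 and adjusted p = 2.5e-01, with Mki67 up by 1.16 ± 0.06 and Ccnb1 down by 0.87.

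Most stress lists rose on average. The cell-cycle inhibitor Cdkn1a rose by 1.85 ± 0.05 (7.7e-16), Btg2 by 1.93 ± 0.05, the apoptosis gene Pmaip1 by 1.88 and the p53 inhibitor Mdm2 by 0.85 ± 0.04 (1.9e-12). Of 24 p53 targets 14 rose and 3 fell (14 and 3 adjusted over the list alone), at a median of 0.24 and adjusted p = 2.8e-03 (1.1e-01 with an estimated correlation). Of 23 integrated stress response genes 16 rose and 3 fell (16 and 3 adjusted over the list alone), at a median of 0.59 and adjusted p = 3.0e-05 (1.1e-01 with an estimated correlation), led by Atf3 at 3.38 ± 0.05. Of 22 endoplasmic reticulum chaperones 16 rose (16 adjusted over the list alone), at a median of 0.37 and adjusted p = 2.7e-05 (1.1e-01 with an estimated correlation), with Hspa5 up by 0.94. Of 26 inflammatory and secretory genes 16 rose and 8 fell (16 and 8 adjusted over the list alone), at a median of 0.49 and adjusted p = 4.7e-03 (8.2e-02 with an estimated correlation). The cytokine Il6 rose by 2.29 ± 0.11.

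On average over the mutants, ribosomal protein genes had 19 of 45 up (13 adjusted over the list alone), at a median of 0.12 and adjusted p = 7.2e-03 (6.8e-01 with an estimated correlation), with Rpl22 up by 0.41. Epithelial markers had 5 of 5 up (5 adjusted over the list alone), at 0.69 and adjusted p = 1.4e-02 (1.1e-01 with an estimated correlation), with the keratin Krt19 up by 3.55 ± 0.13. Muscle markers had 7 of 8 up (7 adjusted over the list alone), at 0.75 and adjusted p = 6.0e-03 (1.9e-01 with an estimated correlation), with the contractile genes Cnn1 up by 1.25 ± 0.14 and Tagln by 1.01 ± 0.07. Lists without a call were cholesterol synthesis, with 7 up and 10 down of 24 (7 and 12 adjusted over the list alone) and adjusted p = 4.2e-01, extracellular matrix, with 17 up and 13 down of 37 (18 and 14) and 3.3e-01, and interferon response, with 14 up and 8 down of 30 (15 and 8) and 1.9e-01. The NRF2 list had 7 up and 14 down of 22 (8 and 14) and 2.9e-01, the histones 5 up and 1 down of 9 (5 and 1) and 2.2e-01, the neural markers 3 up and 2 down of 7 (3 and 2) and 4.6e-01, and the adipocyte markers 1 up and 2 down of 5 (1 and 2) and 4.2e-01. Endothelial and myeloid markers had 4 measured members each and were not tested; 3 rose and 1 fell of the former, and 2 rose and 1 fell of the latter. Of 23 lists tested 14 were called, and HIF targets alone held with an estimated correlation.

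Averaged over the mutants 10897 of 16157 genes were called, or 67.4%, with 5049 up and 5848 down; 844 rose and 262 fell at least 2-fold. In single mutants the calls were 7757 in GLAD (3545 up, 4212 down; 911 and 342 at least 2-fold), 8735 in TIN (4367 and 4368; 1089 and 646) and 9064 in the double mutant (4237 and 4827; 1203 and 833). Of these 1690 genes rose in all 3, against 251 expected if the calls were independent, and 1705 fell in all 3, against 340. Across genes the hypoxia effects correlated at a Pearson r of 0.60 for GLAD with TIN, 0.77 for GLAD with the double mutant and 0.50 for TIN with the double mutant. Genes are not independent of one another, so no p-value is attached.

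**Figure D3:**
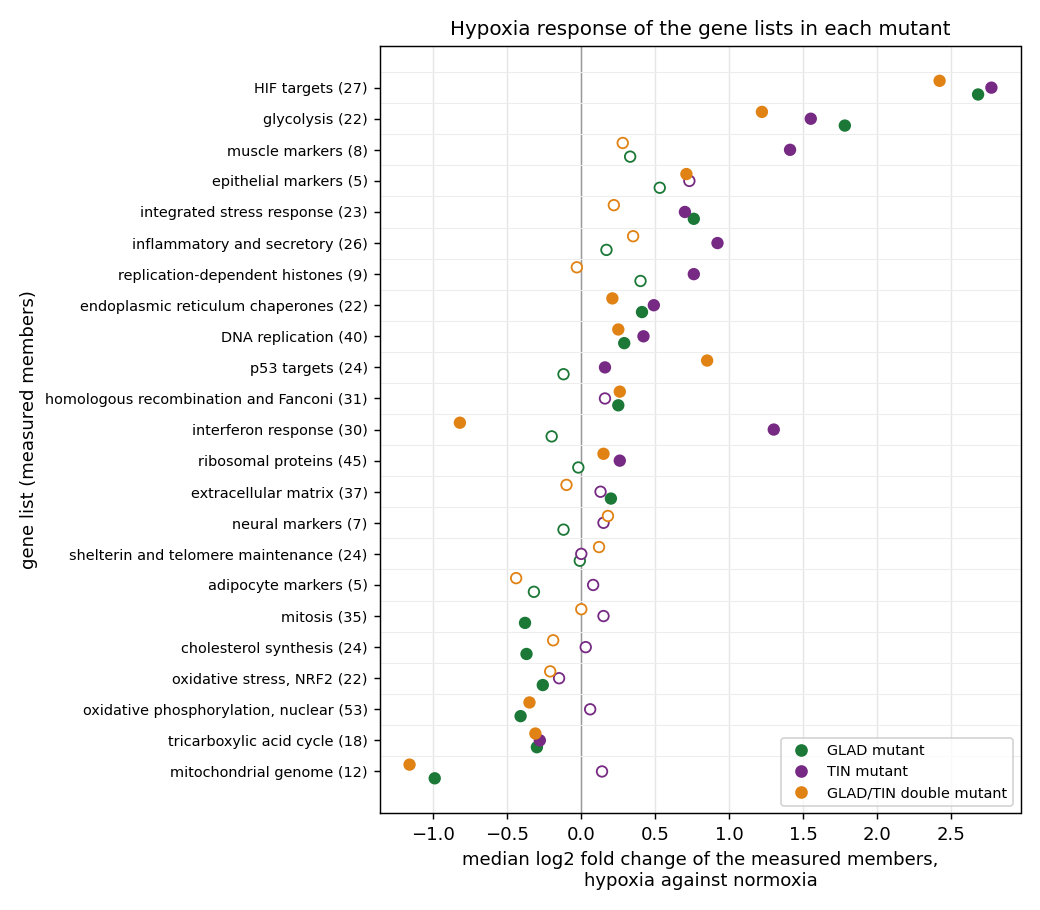
Median log2 fold change in hypoxia against normoxia of the measured members of 23 gene lists, with the number of members in parentheses, for the GLAD, TIN and double mutants. Filled circles are lists called by camera with the preset correlation and open circles are not; HIF targets sit at 2.42 to 2.77 in all 3 mutants, while interferon response genes sit at 1.30 in TIN and −0.82 in the double mutant.

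In the GLAD mutant hypoxia raised glycolysis most among the mutants by median. Pdk1 rose by 3.30, Hk2 by 3.13, Slc2a1 by 2.77, Pgk1 by 2.00, Ldha by 1.96 and Gapdh by 1.50, while Car9 rose by 4.16, Bnip3 by 3.03 and Vegfa by 2.82. Glycolysis had 18 of 22 members up and 1 down (19 and 1 adjusted over the list alone), at a median of 1.78 and adjusted p = 4.7e-19, and HIF targets had 27 of 27 up (27), at 2.68 and 4.0e-34. These 2 lists held with an estimated correlation, at 4.5e-02 and 8.6e-03. Respiratory genes fell, with 47 of 53 nuclear members down (47) at −0.41 and adjusted p = 2.6e-10 (3.3e-01 with an estimated correlation). Mitochondrially encoded genes had 9 of 12 down (10) at −0.99 and 1.1e-03 (3.5e-01), with mt-Cytb down by 1.42. Mitosis genes also fell, 26 of 35 down and 3 up (26 and 3), at −0.38 and 3.4e-06 (2.3e-01 with an estimated correlation), with Ccnb1 down by 1.20, Ube2c by 1.16 and the kinase Plk1 by 1.13. Cdkn1a rose by 0.24 ± 0.08 (2.4e-02), Mdm2 by 0.43, and the p53 list was not called (median −0.12, 5.4e-01).

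Other GLAD genes with large hypoxia changes were Aire, up by 5.63, Trpm2, up by 5.40, and Pif1, down by 2.29 ± 0.13. Terf1 fell by 0.72 ± 0.09 (2.8e-06). Replication genes had 24 up and 4 down of 40 (24 and 6 adjusted over the list alone), at 0.29 and adjusted p = 4.2e-05 (2.0e-01 with an estimated correlation), and cholesterol synthesis had 3 up and 15 down of 24 (3 and 15), at −0.37 and 3.3e-03 (1.7e-01). The integrated stress response had 16 up and 2 down of 23 (16 and 2), at 0.76 and 2.6e-08 (1.1e-01). The matrix list had 17 up and 10 down of 37 (20 and 10), at 0.20 and 1.0e-02 (4.5e-01), and without GLAD hypoxia library B it stood at 0.15 and 5.9e-02. The fall of the NRF2 list, at −0.26 and 4.8e-02, was marginal. It was not called without GLAD normoxia library B (−0.24, 6.9e-02), GLAD hypoxia library A (−0.19, 1.0e-01) or double-mutant normoxia library A or B (−0.26, 5.0e-02 each), or with the length and GC trend removed (−0.30, 5.2e-02).

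In the TIN mutant hypoxia raised interferon genes as well as the oxygen response. Car9 rose by 5.69 ± 0.09, the secreted hormone Stc1 by 5.14 ± 0.21, Bnip3 by 3.62, Pdk1 by 2.99, Vegfa by 2.55, Slc2a1 by 2.53, Hk2 by 2.45, Ldha by 1.80, Pgk1 by 1.75 and Gapdh by 1.19. Cdkn1a rose by 2.99 ± 0.08 (7.5e-15), from 29.3 to 235 CPM, and Mdm2 by 0.50. Of 30 interferon response genes 28 rose and 1 fell (28 and 1 adjusted over the list alone), at a median of 1.30 and adjusted p = 4.2e-18. The innate sensor Zbp1 rose by 2.95, the chemokine Cxcl10 by 2.85, the antiviral enzyme Oas2 by 2.44 and the transcription factor Irf7 by 2.28. Inflammatory genes had 19 up and 3 down of 26 (19 and 5), at 0.92 and 3.7e-07, with Lcn2 up by 3.69 and Il6 by 2.79. Glycolysis had 20 of 22 up (20), at 1.55 and 2.4e-15, and HIF targets 26 of 27 up (26), at 2.77 and 3.6e-27. These 4 lists held with an estimated correlation, at 4.4e-03 for interferon, 5.7e-03 for inflammatory genes, 4.1e-02 for glycolysis and 5.7e-03 for HIF targets.

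Respiratory genes did not fall as a list in the TIN mutant in hypoxia. Nuclear oxidative phosphorylation had 9 up and 8 down of 53 (7 and 7 adjusted over the list alone), at a median of 0.06 and adjusted p = 6.4e-01, and the mitochondrial genome had 3 of 12 up (none alone), at 0.14 and 4.6e-01. Ribosomal protein genes had 24 of 45 up (24), at 0.26 and 2.5e-04 (5.7e-01 with an estimated correlation). The effect in this mutant ran with transcript length, at a Spearman rho of −0.27 across 11940 genes, so that short transcripts gained, against 0.18 in GLAD and 0.09 in the double mutant. With each library's trend on length and GC content removed, the ribosomal list stood at 0.10 (4.7e-02), with 14 up and 1 down, and nuclear oxidative phosphorylation at −0.04, with 6 up and 19 down. Terf1 fell by 0.66 (5.4e-06). Muscle markers had 6 of 8 up (6), at 1.41 and 1.1e-03 (1.4e-01), with Myl9 up by 2.56 ± 0.15. The p53 list, with 10 up and 4 down of 24 (10 and 4), had a median of 0.16, a mean of 0.47 and 1.7e-02 (1.8e-01), 5.7e-02 in a fit of the compared groups alone, and a median of 0.28 with the length and GC trend removed. The call for histones, with 6 of 9 up (6) at 0.76 and 3.2e-02 (4.9e-01), ended without TIN normoxia library A (0.72, 5.1e-02) or TIN hypoxia library B (0.72, 5.8e-02).

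In the double mutant hypoxia raised p53 targets and lowered interferon genes. Pmaip1 rose by 3.01, the kinase Plk2 by 2.74, Cdkn1a by 2.32 and Mdm2 by 1.63. Of 24 p53 targets 16 rose and 2 fell (18 and 2 adjusted over the list alone), at a median of 0.85 and adjusted p = 2.4e-07. Of 30 interferon genes 3 rose and 25 fell (3 and 25), at −0.82 and 4.4e-09, with Ifit3 down by 1.76, the RNA sensor Ifih1 by 1.71 and Oas2 by 1.48. HIF targets had 26 of 27 up (26), at 2.42 and 1.3e-24. With an estimated correlation the values were 2.8e-02 for p53 targets, 2.0e-02 for interferon genes and 2.0e-02 for HIF targets. Glycolysis had 17 of 22 up (17), at 1.22 and 6.9e-12 (7.5e-02 with an estimated correlation), with Hk2 up by 2.13, Pdk1 by 1.94, Pgk1 by 1.38, Gapdh by 1.24 and Ldha by 1.19. Car9 rose by 3.17, Slc2a1 by 2.26, Vegfa by 2.25 and Bnip3 by 2.21.

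Other changes in the double mutant in hypoxia included rises of Fibcd1, by 6.16 ± 0.23, Gipr, by 5.90, and Krt19, by 4.27. The antioxidant genes Gclc and Hmox1 rose by 1.78 and 1.65. Hopx fell by 2.92, together with its antisense neighbour Hopxos, by 2.59, and the interferon-inducible GTPase Ifi47 fell by 2.48 ± 0.17. Terf1 fell by 0.48 (1.3e-04). Nuclear respiratory genes had 39 of 53 down (40 adjusted over the list alone), at −0.35 and adjusted p = 9.6e-07 (5.1e-01 with an estimated correlation), and mitochondrially encoded genes 9 of 12 down (9), at −1.16 and 8.5e-04 (4.5e-01), with mt-Cytb down by 2.21. Ribosomal protein genes had 11 of 45 up (8), at 0.15 and 2.8e-02 (8.0e-01). That call ended without double-mutant normoxia library A (0.09, 1.5e-01) or double-mutant hypoxia library B (0.05, 5.6e-01), and with CPM not scaled further (0.09, 7.6e-02). Mitosis (median 0.00, 9.7e-01) and the integrated stress response (0.22, 1.3e-01) were not called.

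Differences of the hypoxia effect between mutants were tested next, and ask whether the substitutions alter the response to low oxygen. TIN minus GLAD gave 5551 called genes, 2909 positive and 2642 negative, with 595 and 598 at least 2-fold. The response of Cdkn1a was larger in TIN by 2.75 ± 0.12 (9.3e-11), of Car9 by 1.53 ± 0.13 (3.7e-07), of Bnip3 by 0.59 (8.6e-04) and of the interferon effector Isg15 by 2.44 ± 0.12 (5.0e-10). That of Hk2 was smaller by 0.68 ± 0.14 (1.2e-03), while Ldha, at −0.16 (2.8e-01), and Terf1, at 0.05 ± 0.12 (7.6e-01), were not called. The acute-phase genes Serpina3n and Lcn2 differed by 3.17 and 2.71 ± 0.14, the growth regulator Dlk1 by −3.10 and the bicarbonate carrier Slc4a4 by −2.51. Interferon genes had 27 positive and 1 negative of 30 (27 and 1 adjusted over the list alone), at 1.58 and adjusted p = 5.4e-25, and inflammatory genes 19 positive and 1 negative of 26 (20 and 2), at 0.71 and 1.3e-07. These 2 held with an estimated correlation, at 1.5e-03 and 4.8e-03.

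Respiration, division and stress lists also differed between the TIN and GLAD responses. Nuclear respiratory genes had 40 of 53 positive (42 adjusted over the list alone), at 0.47 and adjusted p = 1.4e-10 (4.6e-01 with an estimated correlation), with Atp5e at 1.19 ± 0.19 and Cox6c at 0.90. Mitochondrially encoded genes had 9 of 12 positive (9), at 1.24 and 1.3e-04 (4.6e-01), with mt-Nd4 at 1.49. Mitosis had 27 of 35 positive (27), at 0.53 and 2.9e-11 (1.4e-01), with Ccnb2 at 1.25 and Kif2c at 0.99. The p53 list had 13 positive and 2 negative of 24 (13 and 3), at 0.40 and 1.8e-04 (9.5e-02), and cholesterol synthesis 13 of 24 positive (14 with 1 negative), at 0.44 and 1.2e-04 (8.3e-02), with Fdps at 0.88. Ribosomal protein genes had 14 of 45 positive (6), at 0.31 and 1.3e-04 (7.9e-01), and muscle markers 4 of 8 (4), at 0.88 and 5.6e-03 (3.0e-01). This difference ran with transcript length at a Spearman rho of −0.47 across genes. With each library's trend on length and GC content removed, the ribosomal list stood at 0.08 (4.3e-01) and nuclear respiratory genes at 0.25.

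The difference in glycolysis between TIN and GLAD depended on the processing. It had 4 positive and 7 negative of 22 (4 and 10 adjusted over the list alone), at −0.23 and adjusted p = 4.9e-02 (7.5e-01 with an estimated correlation), with Pfkfb3 at −0.96 and the lactate carrier Slc16a1 at −0.73. That marginal call ended without GLAD normoxia library A (−0.21, 1.0e-01), TIN normoxia library A (−0.20, 6.8e-02), double-mutant normoxia library A (−0.23, 5.2e-02) or B (−0.23, 5.3e-02), GLAD hypoxia library B (−0.16, 2.2e-01), TIN hypoxia library B (−0.20, 9.1e-02) or wild-type library A (−0.23, 5.7e-02) or B (−0.21, 6.4e-02). With the length and GC trend removed it was larger and still called, at −0.43, with 14 of 22 negative and none positive. HIF targets had 8 positive and 9 negative of 27 (8 and 10), and their median of 0.10 and the downward direction of the list test (9.6e-01) had opposite signs; with that trend removed the median was 0.02. Adm differed by 2.42, Ddit4 by 2.19 and the glycogen enzyme Gbe1 by −1.92. Telomere genes, with 3 positive and 6 negative of 24 (4 and 7), were not called as a list (−0.07, 2.4e-01). With the length and GC trend removed they stood at −0.14. With it left in, the tankyrases Tnks and Tnks2 stood at −1.05 and −0.97, Atrx at −0.99, Atm at −1.24 and Atr at −1.03.

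The double mutant minus GLAD asks what adding the TIN substitution to GLAD did to the response. It gave 2372 called genes, 1170 positive and 1202 negative, with 331 and 344 at least 2-fold. The glycolytic response was smaller in the double mutant, by 1.36 ± 0.12 for Pdk1 (2.1e-06), 1.18 for Slc16a3, 1.01 ± 0.14 for Hk2 (8.3e-05), 0.77 ± 0.11 for Ldha (1.3e-04), 0.62 for Pgk1 (4.3e-04) and 0.50 for Slc2a1 (3.1e-03). Glycolysis had 1 positive and 15 negative of 22 (1 and 17 adjusted over the list alone), at −0.47 and adjusted p = 1.1e-10 (adjusted p = 8.8e-02 with an estimated correlation). HIF targets had 6 positive and 11 negative of 27 (6 and 16), at −0.30 and 8.0e-04 (2.5e-01), with Stc2 at −1.56, Ak4 at −1.20, Car9 at −0.99 (7.7e-05), Bnip3 at −0.82 and Vegfa at −0.57 (8.9e-04). Gapdh, at −0.26 (1.6e-01), and Terf1, at 0.24 ± 0.12 (2.2e-01), were not called. In normoxia this mutant already had higher glycolytic levels than GLAD: the glycolysis list summed over deposited CPM, without TMM scaling, held 9334 ± 5.66 CPM against 6356 ± 113 CPM (SD, n = 2 each), and in hypoxia 20832 ± 614 against 20124 ± 940 CPM.

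Stress and interferon responses differed as well between the double mutant and GLAD. Of 24 p53 targets 19 were positive and 1 negative (20 and 1 adjusted over the list alone), at 1.03 and adjusted p = 8.0e-22, with Perp at 2.41 ± 0.23, Pmaip1 at 2.14, Cdkn1a at 2.08 (9.4e-09) and Mdm2 at 1.19 (6.2e-07). Interferon genes had 26 of 30 negative (27), at −0.69 and 6.9e-20, with Ifit3 at −1.14. These 2 lists held with an estimated correlation, at 1.6e-03 each. The p53 list started lower in the double mutant. Summed over deposited CPM, it held 1239 ± 12.7 CPM in normoxia, against 2260 ± 28.3 CPM in GLAD (SD, n = 2 each). In hypoxia the sums were 2675 ± 69.3 and 2367 ± 46.7 CPM, and the p53 median of the double mutant against GLAD was 0.09. The integrated stress response had 2 positive and 13 negative of 23 (2 and 13), at −0.54 and 1.7e-07 (8.8e-02), with the asparagine synthetase Asns at −1.45. The matrix list had 1 positive and 20 negative of 37 (1 and 24), at −0.42 and 8.8e-12 (1.1e-01), with Tnc at −1.14 and Col3a1 at −1.10. Mitosis had 17 of 35 positive (25), at 0.38 and 3.0e-13 (8.8e-02), cholesterol synthesis 6 of 24 (8), at 0.20 and 2.6e-04 (8.8e-02), and the NRF2 list 8 positive and 1 negative of 22 (10 and 1), at 0.24 and 8.9e-04 (1.9e-01), with Hmox1 at 1.31. Nuclear respiratory genes, at 0.04 (5.9e-01), and telomere genes, at 0.05 (8.6e-01), were not called. Ribosomal protein genes, with 2 of 45 positive (none alone) at 0.17 and 6.6e-04 (8.2e-01), fell to 0.06 (2.9e-01) without double-mutant hypoxia library B. The count of called genes fell without most single GLAD or double-mutant libraries and rose without either wild-type library. The wild type, with the widest spread (12.6%), enters only through the shared variance, scaling and filter. A fit of the compared groups alone gave 3288.

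The double mutant minus TIN gave the widest difference, with 6963 called genes, 3349 positive and 3614 negative, and 970 and 1100 at least 2-fold. Car9 stood at −2.52 ± 0.13 (2.7e-10), Slc16a3 at −1.73, Bnip3 at −1.41, Pdk1 at −1.05 (4.8e-06), Cdkn1a at −0.66 (2.3e-04) and Ldha at −0.61 (2.5e-04), and Mdm2 at 1.13 (1.1e-07). The kinase Stk39 and the calcium channel Cacna1h stood at 3.98 and 3.85, and Zbp1, Oas2 and Ifi47 at −4.11, −3.92 and −3.90. Terf1 was not called, at 0.18 (2.3e-01). Interferon genes had 29 of 30 negative (29 adjusted over the list alone), at −1.96 and adjusted p = 7.5e-31, and inflammatory genes 2 positive and 15 negative of 26 (2 and 16), at −0.48 and 1.5e-04. These 2 held with an estimated correlation, at 7.4e-04 and 2.9e-02, and stood at −1.90 and −0.31 with the length and GC trend removed. Nuclear respiratory genes had 33 of 53 negative (37), at −0.45 and 4.0e-07 (4.9e-01), and mitochondrially encoded genes 9 of 12 (9), at −1.60 and 1.1e-04 (4.9e-01), in a comparison that ran with length at a rho of 0.35. With that trend removed they stood at −0.25 (5.8e-04) and −1.56 (9.4e-05).

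Stress lists differed between the double mutant and TIN too. P53 targets had 13 positive and 3 negative of 24 (13 and 3 adjusted over the list alone), at 0.66 and adjusted p = 2.0e-03 (2.4e-01 with an estimated correlation), with Aen at 1.86. The integrated stress response had 2 positive and 16 negative of 23 (3 and 17), at −0.61 and 1.0e-04 (2.9e-01), with Chac1 at −2.25, and the matrix list 4 positive and 22 negative of 37 (4 and 23), at −0.43 and 2.9e-05 (4.9e-01), with Postn at −2.17. Glycolysis had 1 positive and 9 negative of 22 (1 and 9), at −0.26 and 1.1e-02 (4.9e-01), and −0.19 (9.2e-02) with the length and GC trend removed. HIF targets were not called at −0.25 (7.4e-02), but were without TIN normoxia library B (−0.30, 4.0e-02) or double-mutant hypoxia library A (−0.33, 1.8e-02). Histones, with 5 of 9 negative (5) at −0.96 and 4.1e-02 (4.9e-01), lost their call without TIN hypoxia B (−0.92, 5.9e-02), double-mutant normoxia B (−1.04, 5.1e-02), double-mutant hypoxia A (−0.72, 8.7e-02), wild-type A (−0.96, 6.2e-02) or B (−0.97, 7.2e-02), or TIN normoxia A, where the median lay within that range (5.7e-02), and with the length and GC trend removed (−0.85, 6.3e-02).

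The mutants were then set against wild-type NMR TRF1 in normoxia. Igfbp2, which binds insulin-like growth factors (ENSMUSG00000039323, GRCm38 chromosome 1, 72824503 to 72852474), fell to log2 differences of −5.19 in GLAD, −9.84 in TIN and −6.28 in the double mutant, from 1165 ± 93.5 CPM in the wild type to 31.3, 0.781 and 14.4 CPM. In the same order Megf6 fell to −4.98, −6.89 and −6.45, and the developmental factor Eomes to −3.68, −6.24 and −5.68. The metalloreductase Steap4 rose by 7.43, 2.68 and 8.82, from 0.382 CPM in the wild type, which is near the floor. The matrix proteoglycan Vcan rose by 5.11, 4.55 and 5.27. Terf1 rose by 0.64 ± 0.09 (7.9e-06), 0.90 ± 0.09 (7.2e-08) and 0.47 ± 0.09 (1.6e-04). In all 3 mutants 2259 genes rose, against 377 expected if independent, and 2221 fell, against 389. The 2 control libraries enter each comparison and may give part of this overlap. Simulations without any effect or batch gave 0 genes after adjustment, and 39.8 and 40.8 without it. They cannot judge that part, and the control libraries were not split. Any batch of the wild-type libraries would also appear here. In a fit of the compared groups alone the number that rose in all 3 was 1433.

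GLAD against wild type gave 8946 called genes, 4410 up and 4536 down, with 1206 and 699 at least 2-fold. P53 targets were higher: Ddit4l rose by 3.55, the receptor Eda2r by 1.83, Cdkn1a by 1.06 ± 0.08 (9.8e-09) and Mdm2 by 0.81. The list had 18 up and 2 down of 24 (19 and 2 adjusted over the list alone), at 0.65 and adjusted p = 2.0e-06 (8.9e-02 with an estimated correlation). Inflammatory genes had 14 up and 6 down of 26 (14 and 7), at 0.40 and 7.9e-03 (8.9e-02), with Igfbp3 up by 5.22 and the adhesion molecule Icam1 by 4.16. Cholesterol synthesis had 1 up and 17 down of 24 (1 and 17), at −0.54 and 7.6e-05 (8.9e-02), with Cyp51 down by 1.30. Glycolysis, with 7 up and 5 down of 22 (8 and 5), was not called; its median was 0.07, its mean −0.07 and its adjusted p 6.8e-01. Pfkfb3 fell by 2.23, while Ldha, at 0.18 (5.1e-02), was not called; it was called without GLAD hypoxia library A (0.18, 4.3e-02) or B (0.20, 3.3e-02), double-mutant hypoxia library A (0.18, 4.5e-02) or B (0.18, 4.4e-02) or wild-type library B (0.26, 1.6e-02). Car9 rose by 0.64 (2.0e-05) and Bnip3 by 0.69. The matrix genes Dcn and Lum rose by 4.85 and 3.70.

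Housekeeping lists were lower in GLAD than in the wild type. Ribosomal protein genes had 37 of 45 down (39 adjusted over the list alone), at −0.40 and adjusted p = 6.9e-08 (5.6e-01 with an estimated correlation), and nuclear respiratory genes 2 up and 31 down of 53 (2 and 32), at −0.35 and 9.3e-06 (5.6e-01), with Rpl37a down by 1.05 and Atp5h by 0.88. The comparison ran with transcript length at a rho of 0.24, and with the length and GC trend removed the lists stood at −0.39, with 38 of 45 down, and −0.33, with 31 of 53 down. The integrated stress response had 3 up and 17 down of 23 (3 and 17), at −0.52 and 3.3e-04 (3.7e-01), with Trib3 down by 1.51, and mitosis 18 up and 1 down of 35 (18 and 1), at 0.20 and 4.6e-03 (5.6e-01), and 0.10 with that trend removed (14 up and 4 down). Telomere genes had 5 up and 11 down of 24 (5 and 11) and no call (−0.21, 3.1e-01), with the telomerase inhibitor Pinx1 down by 0.90. DNA replication, with 5 up and 17 down of 40 (5 and 17) at −0.16 and 2.8e-02 (5.6e-01), stood at −0.09 (1.0e-01) without wild-type library B. Adipocyte markers, with 3 of 5 up (3) at 0.97 and 4.3e-02 (5.6e-01), were not called without wild-type library A (1.00, 1.3e-01) or GLAD normoxia library B (0.87, 7.0e-02). Mitochondrially encoded genes had 5 of 12 down (5), at −0.44 and 4.8e-02 (6.5e-01), a marginal call that ended without GLAD normoxia library A (−0.53, 5.8e-02) or B (−0.41, 7.0e-02), double-mutant hypoxia library A or B (−0.44, 5.4e-02 each) or wild-type library A (−0.48, 1.1e-01) or B (−0.41, 6.2e-02), or with that trend removed (−0.47, 7.4e-02). None of the 10 lists called in this comparison held with an estimated correlation.

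TIN against wild type gave 9719 called genes, 4814 up and 4905 down, with 1091 and 1654 at least 2-fold. Interferon genes were lower throughout: 30 of 30 fell (30 adjusted over the list alone), at a median of −4.05 and adjusted p = 2.5e-31 (7.0e-04 with an estimated correlation). Oas2 (ENSMUSG00000032690, GRCm38 chromosome 5, 120730333 to 120749853) fell by 7.14 ± 0.08, from 332 ± 17.4 CPM to 1.86 ± 0.198 CPM, while the ubiquitin ligase gene Trim30a stood at −6.43, Zbp1 at −5.71 and the immunoproteasome subunit Psmb8 at −7.02. The class I genes H2-Q7 and H2-Q6, which may share reads, stood at −7.89 and −7.67. P53 targets had 1 up and 19 down of 24 (1 and 19), at −0.61 and 6.4e-05 (1.2e-01), with Perp at −4.81, Btg2 at −2.20 and Cdkn1a at −1.81 ± 0.08 (2.1e-12). The matrix list had 7 up and 25 down of 37 (7 and 25), at −1.06 and 1.6e-04 (3.2e-01), with Col11a1 at −5.70 and Thbs1 at −3.65. The vesicle sensor Syt7 rose by 6.51 ± 0.13 and the Notch target Hey1 by 6.12.

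Telomere, division and glycolysis genes were higher in TIN than in the wild type. Telomere genes had 15 up and 3 down of 24 (15 and 3 adjusted over the list alone), at 0.30 and adjusted p = 1.5e-02 (1.4e-01 with an estimated correlation), with Tnks2 up by 1.29 and Dkc1 by 0.94. Mitosis had 27 of 35 up (27), at 0.51 and 2.8e-07 (2.6e-01), replication 22 up and 1 down of 40 (22 and 3), at 0.25 and 1.3e-03 (3.2e-01), and 0.41 with the length and GC trend removed, and homologous recombination 17 up and 5 down of 31 (17 and 5), at 0.27 and 1.8e-02 (3.2e-01), with Kif11 up by 1.01, Rrm2 by 0.94 and Bard1 by 1.14. The recombination list stood at 0.23 (5.8e-02) with the length and GC trend removed. Ldha rose by 0.80 ± 0.08 (6.7e-08), Slc16a1 by 1.18, Gapdh by 0.43 and Pgk1 by 0.30, while Slc16a3 fell by 2.60 and Pfkfb3 by 3.56. Glycolysis had 15 up and 3 down of 22 (15 and 4), at 0.35 and 1.9e-02 (4.1e-01), and without wild-type library A 0.31 (5.3e-02). HIF targets had 6 up and 15 down of 27 (6 and 15), at −0.27 and 2.7e-02 (4.1e-01), without wild-type library A −0.35 (5.3e-02) and with the length and GC trend removed −0.14 (7 up and 12 down), with Lox down by 4.23 and Car9 by 2.52 ± 0.09. The NRF2 list had 16 up and 3 down of 22 (16 and 3), at 0.44 and 7.6e-04 (2.6e-01), with Gclc up by 2.08. Endoplasmic reticulum chaperones had 15 of 22 down (15), at −0.33 and 1.6e-03 (2.6e-01).

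The double mutant against wild type gave 9197 called genes, 4633 up and 4564 down, with 1306 and 875 at least 2-fold. Sterol synthesis was lower: 24 of 24 members fell (24 adjusted over the list alone), at −0.97 and adjusted p = 1.1e-12, with Cyp51 down by 2.54 ± 0.08 (8.8e-14), Sqle by 1.65 and Fdps by 1.64. Inflammatory genes had 17 up and 4 down of 26 (19 and 4), at 0.84 and 3.0e-05, with Lcn2 up by 4.61 and Saa3 by 3.27. These 2 lists held with an estimated correlation, at 1.0e-02 and 1.6e-02. Glycolysis was higher in normoxia, with 17 up and 2 down of 22 (17 and 2), at 0.72 and 1.0e-06 (3.5e-01), and so were HIF targets, with 19 up and 3 down of 27 (20 and 4), at 0.64 and 5.4e-05 (3.5e-01). Slc16a1 rose by 2.70, Pdk1 by 1.44 ± 0.09 (2.3e-10), Bnip3 by 1.39, Slc2a1 by 1.18 ± 0.07 (3.5e-10), Hk2 by 1.14, Ldha by 1.08 ± 0.08 (2.1e-09), Vegfa by 0.85, Car9 by 0.67, Pgk1 by 0.55 and Gapdh by 0.43. The proteoglycan Dcn rose by 6.59 ± 0.07 and the collagenase Mmp13 by 6.47, and the natriuretic peptide receptor Npr3 fell by 6.04.

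Respiratory genes were lower in the double mutant than in the wild type. Of 53 nuclear members 1 rose and 42 fell (1 and 44 adjusted over the list alone), at −0.49 and adjusted p = 1.3e-09 (4.7e-01 with an estimated correlation), and 12 of 12 mitochondrially encoded genes fell (12), at −1.27 and 5.4e-05 (4.7e-01), with Uqcrq down by 1.24 and mt-Nd3 by 2.25 ± 0.30. The comparison ran with transcript length at a rho of 0.25, and with the length and GC trend removed the lists stood at −0.45, with 44 of 53 down, and −1.18, with 12 of 12 down. Mitosis had 21 up and 1 down of 35 (21 and 1), at 0.30 and 7.8e-04 (4.7e-01), and 0.16 with that trend removed (16 up and 6 down), with Anln up by 0.78 ± 0.11 and Kif11 by 0.76 ± 0.09. Interferon genes had 12 up and 10 down of 30 (12 and 10) and no call (0.04, 8.7e-01). P53 targets (−0.24, 2.0e-01) and telomere genes (0.13, 4.6e-01) were not called. Ribosomal protein genes, with 18 of 45 down (17) at −0.14 and 1.3e-02 (7.7e-01), stood at −0.03 (5.2e-01) without wild-type library B, −0.12 (8.2e-02) without double-mutant normoxia library A and −0.11 (1.7e-01) with that trend removed. The call for the tricarboxylic acid cycle, with 1 up and 10 down of 18 (1 and 10) at −0.24 and 2.9e-02 (4.7e-01), ended at −0.23 (5.6e-02) in a fit of the compared groups alone.

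TIN against GLAD in normoxia gave 8255 called genes, 4102 up and 4153 down, with 413 and 1484 at least 2-fold. Interferon genes had 30 of 30 down (30 adjusted over the list alone), at −3.85 and adjusted p = 3.5e-38, p53 targets 1 up and 23 down of 24 (1 and 23), at −1.46 and 2.8e-14, and inflammatory genes 6 up and 18 down of 26 (6 and 18), at −0.92 and 8.0e-06. Telomere genes were higher, 17 up and 1 down of 24 (17 and 1), at 0.41 and 4.6e-05, with the telomerase components Nhp2 up by 1.13 ± 0.11, Nop10 by 0.99 and Dkc1 by 0.81. These 4 lists held with an estimated correlation, at 3.6e-04, 5.1e-03, 8.6e-03 and 1.1e-02. Replication had 31 of 40 up (31), at 0.43 and 9.4e-10 (5.6e-02 with an estimated correlation), with Mcm5 up by 1.05, and ribosomal protein genes 41 of 45 up (42), at 0.50 and 1.2e-11 (3.1e-01). The matrix list had 6 up and 30 down of 37 (7 and 30), at −0.96 and 7.5e-11 (1.3e-01). Cdkn1a stood at −2.87 ± 0.08 (3.7e-15), Perp at −4.02, Mdm2 at −1.02, Car9 at −3.15, Oas2 at −7.31 ± 0.08 and the matrix gene Postn at −6.31 ± 0.10. Terf1 rose by 0.26 (1.7e-02) and Ldha by 0.62.

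TIN against GLAD in hypoxia gave 10179 called genes, 4917 up and 5262 down, with 728 and 1671 at least 2-fold. Interferon genes had 30 of 30 down (30 adjusted over the list alone), at −2.28 and adjusted p = 2.4e-25, p53 targets 19 of 24 down (19), at −0.95 and 2.4e-07, and cholesterol synthesis 21 of 24 up (21), at 0.83 and 4.3e-09, with Msmo1 up by 1.81. With an estimated correlation the values were 1.4e-03, 3.1e-02 and 1.9e-02. Nuclear respiratory genes had 51 of 53 up (52), at 0.69 and 4.8e-14 (2.4e-01 with an estimated correlation), mitochondrially encoded genes 11 of 12 up (11), at 1.11 and 6.0e-04 (3.2e-01), ribosomal protein genes 45 of 45 up (45), at 0.80 and 4.5e-16 (2.4e-01), and mitosis 32 up and 1 down of 35 (32 and 1), at 0.81 and 8.1e-14 (9.9e-02). Atp5e rose by 1.39, mt-Nd1 by 1.58, Rpl37a by 1.22 and Ube2c by 1.44. This comparison ran with length at a rho of −0.39, against −0.04 in normoxia, and with the length and GC trend removed the nuclear respiratory list stood at 0.49, the ribosomal at 0.64 and the mitotic at 0.95. Cdkn1a was not called, at −0.12 (2.1e-01), while Mdm2 fell by 0.96 and Car9 by 1.62, Ldha rose by 0.47 and Terf1 rose by 0.32 (4.0e-03).

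The double mutant against GLAD gave 5778 called genes in normoxia, 2995 up and 2783 down, with 493 and 579 at least 2-fold. In hypoxia it gave 6917, 3608 up and 3309 down, with 444 and 655 at least 2-fold. In normoxia glycolysis had 17 of 22 up (17 adjusted over the list alone), at 0.54 and adjusted p = 2.2e-11 (8.4e-02 with an estimated correlation), and HIF targets 18 up and 4 down of 27 (18 and 4), at 0.45 and 6.5e-06 (1.3e-01). Slc16a3 rose by 3.01, Slc16a1 by 2.33, Pdk1 by 1.47 ± 0.09 (6.7e-10), Hk2 by 1.40 ± 0.10, Vegfa by 1.08, Slc2a1 by 1.07 and Ldha by 0.89. P53 targets had 1 up and 20 down of 24 (1 and 20), at −0.82 and 1.9e-12, and cholesterol synthesis 20 of 24 down (21), at −0.54 and 4.7e-11; these 2 held with an estimated correlation at 9.0e-03 each, with Cdkn1a down by 1.29. Telomere genes had 8 of 24 up (8), at 0.21 and 7.7e-03 (8.4e-02), and Terf1 was not called at −0.17 (1.4e-01). In hypoxia mitosis had 30 of 35 up (31), at 0.40 and 8.3e-11 (1.5e-01), ribosomal protein genes 36 of 45 up (38), at 0.37 and 4.8e-10 (3.9e-01), the matrix list 6 up and 26 down of 37 (6 and 26), at −0.48 and 8.1e-08 (2.3e-01), interferon genes 4 up and 23 down of 30 (4 and 23), at −0.54 and 1.1e-07 (6.7e-02), and mitochondrially encoded genes 9 of 12 down (9), at −1.06 and 4.2e-05 (3.9e-01). None of the 15 lists called in hypoxia held with an estimated correlation. Glycolysis in hypoxia, at 0.12 and 4.8e-02 (4.5e-01), was marginal and stood at 0.07 (2.0e-01) without GLAD hypoxia library A and 0.08 (1.5e-01) without double-mutant hypoxia library A, and had 6.3e-02 with the length and GC trend removed.

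The double mutant against TIN gave 7644 called genes in normoxia, 3932 up and 3712 down, with 1395 and 443 at least 2-fold. In hypoxia it gave 10345, 5367 up and 4978 down, with 1703 and 981 at least 2-fold. Interferon genes had 30 of 30 up in normoxia (30 adjusted over the list alone), at 4.11 and adjusted p = 8.2e-42, and 30 of 30 up in hypoxia (30), at 2.04 and 1.3e-21 (2.7e-04 and 2.4e-03 with an estimated correlation). Cholesterol synthesis had 23 of 24 down in normoxia (23), at −0.90 and 1.1e-13 (4.2e-03), and 22 of 24 down in hypoxia (22), at −1.05 and 5.0e-12 (6.9e-03). Inflammatory genes had 17 up and 4 down of 26 in normoxia (17 and 4), at 0.87 and 3.2e-07 (4.2e-03), and HIF targets 25 of 27 up (25), at 0.94 and 8.8e-14 (3.0e-02), with Car9 up by 3.19, Slc16a3 by 3.70, Lcn2 by 6.94 and Cdkn1a by 1.58. In hypoxia p53 targets had 19 of 24 up (19 with 1 down), at 0.91 and 5.2e-08 (2.1e-02), with Pmaip1 up by 2.94, Mdm2 by 1.66 and Cdkn1a by 0.91. Nuclear respiratory genes had 53 of 53 down in hypoxia (53), at −0.74 and 1.5e-16 (2.5e-01), and mitochondrially encoded genes 11 of 12 down (11), at −2.55 and 9.2e-07 (2.5e-01), in a comparison that ran with length at a rho of 0.35, and stood at −0.62 and −2.50 with the length and GC trend removed. Terf1 fell by 0.43 in normoxia (4.8e-04) and by 0.25 in hypoxia (1.8e-02).

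Differences between the mutants also ran along chromosomes. For TIN against GLAD in normoxia the median difference of all genes on a chromosome was 0.31 on chromosome 17, 0.30 on chromosome 2, 0.28 on chromosome 8 and −0.25 on chromosome 18. On the Y chromosome, with 6 genes, it was −1.13, and the Y-linked helicase Ddx3y stood at 16.3 ± 3.16 CPM in TIN against 61.1 ± 1.53 CPM in GLAD in normoxia (SD, n = 2 each). The medians of the 21 chromosomes in normoxia and in hypoxia, from separate libraries, had a Spearman rho of 0.94, and 0.94 without the Y chromosome. For the double mutant against GLAD and against TIN the rho was 0.87 and 0.88. Medians of 229 windows of 50 neighbouring genes spread 2.65 times as widely as in random gene orders for TIN against GLAD in normoxia, and 1.34, 1.65 and 1.42 times for the hypoxia effect within GLAD, TIN and the double mutant.

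**Figure D4:**
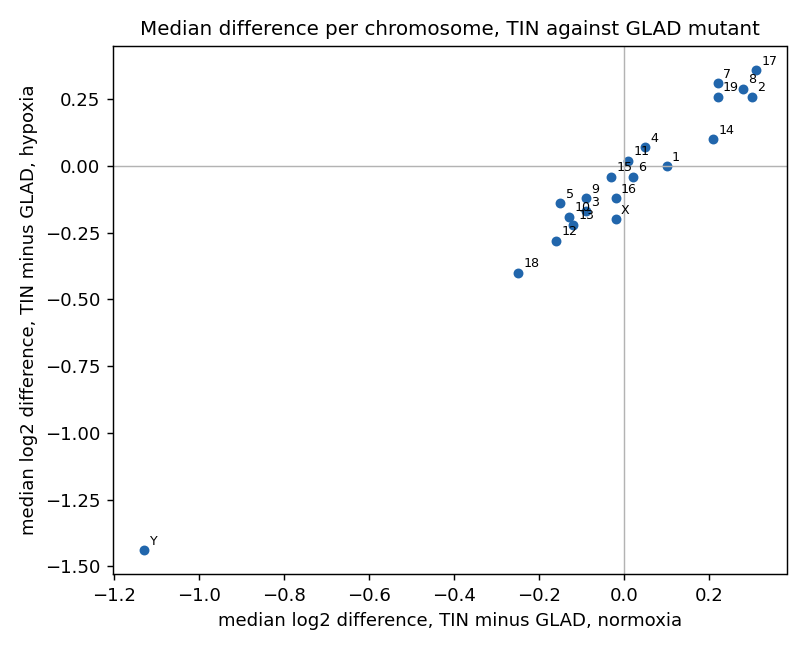
Median log2 difference of the genes on each of 21 chromosomes, TIN minus GLAD mutant, in normoxia on the horizontal axis and in hypoxia on the vertical axis, with 1 point per chromosome. Chromosomes 17, 2 and 8 lie at 0.28 to 0.31 in normoxia, chromosome 18 at −0.25 and the Y chromosome at −1.13, and the ranks in the 2 conditions have a Spearman rho of 0.94.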

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

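The tests named here as made on the TIN substitution and on the cell line were chosen after the result was seen; the tests on chromosome position and paralogs were chosen before. The bounds for transcript length and GC content were set before the corrected values were seen, but that correction was chosen after the first results. Each result in this part stands out because the hypoxia effect differed between 2 mutants by a direct test of that difference in limma.

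The numbers of genes with such a difference were 5551 for TIN minus GLAD, 2372 for the double mutant minus GLAD and 6963 for the double mutant minus TIN. The count of 2372 was 1454 without GLAD normoxia library B and 3630 without wild-type library B, and lay at 1462 to 3623 in the other 7 cases that moved it over 1.5-fold: 1462 without GLAD normoxia A, 1499 and 1573 without double-mutant normoxia A and B, 1534 and 1567 without GLAD hypoxia A and B, 1517 without double-mutant hypoxia A and 3623 without wild-type A.

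The interferon response was the widest difference among the lists in both comparisons with TIN, while p53 targets were in the double mutant minus GLAD, at 1.03. Its median was 1.58 for TIN minus GLAD, −0.69 for the double mutant minus GLAD and −1.96 for the double mutant minus TIN. In TIN minus GLAD Oas2 stood at 3.09 and Zbp1 at 3.02. In the double mutant minus TIN Zbp1 stood at −4.11, Oas2 at −3.92, Ifi47 at −3.90 and the apolipoprotein gene Apol6 at −3.56.

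The rise in TIN started from a low level, with a median over members of 13.9 CPM in normoxia and 38.0 CPM in hypoxia. With the normoxia libraries of the other genotypes averaged together, the median was 208 CPM. Of 28 members at least 4-fold lower in TIN than GLAD in normoxia, 17.9% lay on 1 chromosome, the rest on 12 others. This argues against 1 lost region holding them, not 1 acting on them. The median was −3.42 over 15 members alone in their symbol family in the list. Paralogs outside it were not excluded. In the double mutant, with the same TIN substitution, the median against wild type was 0.04, so low levels did not go with the substitution in both lines. In hypoxia the TIN libraries still lay at −2.28 against GLAD. A property of a cell line or culture and an effect of the substitution cannot be told apart, because each genotype may be 1 line.

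Respiratory genes differed where TIN was compared. The nuclear oxidative phosphorylation list stood at 0.47 for TIN minus GLAD and −0.45 for the double mutant minus TIN, and the mitochondrial genome at 1.24 and −1.60, but these calls ended with an estimated correlation (4.6e-01 or 4.9e-01). With the length and GC trend removed, the nuclear list stood at 0.25 for TIN minus GLAD, with 22 of 53 still positive. The double mutant minus TIN stood at −0.25, with 3 positive and 22 negative. A length bias and a change in these short transcripts cannot be told apart there, as the value lies between the bounds set beforehand. The mitochondrial genome stood at 1.15 after that removal, which argues against such a bias alone. Its summed CPM had a normoxia SD of 2005 in TIN and 116 in GLAD, so library spread was not excluded. The double mutant minus GLAD stood at 0.04 for the nuclear list, so the difference did not go with the TIN substitution in both lines.

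The remaining lists are given as values; with an estimated correlation only inflammatory genes in both comparisons with TIN and p53 targets in the double mutant minus GLAD kept their calls. For TIN minus GLAD the medians were −0.23 for glycolysis, 0.53 for mitosis, 0.40 for p53 targets, 0.44 for cholesterol synthesis, 0.71 for inflammatory genes, 0.31 for ribosomal proteins (0.08 and no call with the length and GC trend removed) and 0.88 for muscle markers. The double mutant minus GLAD gave −0.47 for glycolysis, −0.30 for HIF targets, 0.38 for mitosis, 1.03 for p53 targets, 0.20 for cholesterol synthesis, −0.54 for the integrated stress response, −0.42 for extracellular matrix, 0.24 for the NRF2 list and 0.17 for ribosomal proteins. The double mutant minus TIN gave −0.26 for glycolysis, 0.66 for p53 targets, −0.61 for the integrated stress response, −0.43 for extracellular matrix, −0.48 for inflammatory genes and −0.96 for histones. Ribosomal proteins in the double mutant minus GLAD lost their call without double-mutant hypoxia library B (0.06), and histones without double-mutant hypoxia library A (−0.72) and 5 further libraries named in the results, in which the median was −1.04 to −0.92. Glycolysis in TIN minus GLAD lost its call without any 1 of 8 libraries, at −0.23 to −0.16, and was larger and called, at −0.43, with the length and GC trend removed.

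Single genes with the widest differences are also given as values. In TIN minus GLAD, Serpina3n stood at 3.17, the matrix gene Tnn at 3.15, Dlk1 at −3.10, Trpm2 at −2.84, Slc4a4 at −2.51 and Apol7d at −2.33. In the double mutant minus GLAD, the junction protein Evpl stood at 3.31, the membrane protease Mmp15 at 3.00, Cacna1h at 2.98, Fibcd1 at 2.54, Tcim at −1.99, Lrrn4cl at −1.98, Slc4a4 at −1.93 and Sema5a at −1.90. In the double mutant minus TIN, Stk39 stood at 3.98, Cacna1h at 3.85, Trpm2 at 3.05 and Evpl at 2.96.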

How the results depend on the processing

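Of the alternatives, 4 were chosen after the first results were seen: the pseudocounts of 0.1 and 2 CPM, the library weights and the removal of length and GC trends. Over all alternatives 3 of 20 counts, 36 of 204 list results and 744 of 844 gene results were kept throughout. A count was kept if it stayed within 1.5 times its main value, and a list or gene result if its direction and its side of the threshold stayed. The list results include 2 tests of HIF targets without a call. The minimum fold lowered the 16 counts it was applied to, and the estimated correlation ended 166 list calls. Leaving out single libraries weakened 348 gene results and 66 list results, counted once for each library left out, strengthened 17 and 2 and turned the direction of 8 and 2; the cause of these changes was not tested. With limma-voom on the recovered reads all 20 counts and 204 lists were kept in this sense, and so were all 20 counts with a term for the library letter. The DESeq2 Wald test planned as an alternative was not run, since the deposited values were CPM, and the scalings and filters were run in the limma fit.

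At a fold of at least 2 the hypoxia counts were 1253 in GLAD, 1735 in TIN, 2036 in the double mutant and 1106 on average. The differences of the hypoxia effect gave 1193 for TIN minus GLAD, 675 for the double mutant minus GLAD and 2070 for the double mutant minus TIN. Against wild type the counts were 1905, 2745 and 2181 for GLAD, TIN and the double mutant. In normoxia and hypoxia they were 1897 and 2399 for TIN against GLAD, 1072 and 1099 for the double mutant against GLAD, and 1838 and 2684 for the double mutant against TIN. In a fit of the compared groups alone 1433 genes rose in all 3 mutants against wild type. Without single libraries the double mutant minus GLAD ranged from 1454 (without GLAD normoxia B) to 3630 (without wild-type B).

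With an estimated correlation the glycolysis call ended at 1.22 (7.5e-02) in the double mutant in hypoxia, 1.55 (8.2e-02) on average, −0.23 (7.5e-01) for TIN minus GLAD, −0.47 (8.8e-02) for the double mutant minus GLAD and −0.26 (4.9e-01) for the double mutant minus TIN, and the HIF call at −0.30 (2.5e-01) for the double mutant minus GLAD. Glycolysis for TIN minus GLAD was also not called at −0.23 with median-of-ratios scaling (5.3e-02), the library letter (5.4e-02) or a pseudocount of 2 CPM (5.1e-02), and without single libraries ranged from −0.29 (without GLAD hypoxia A) to −0.16 (without GLAD hypoxia B). With length and GC trends removed it was larger and called, at −0.43. For the double mutant minus TIN glycolysis stood at −0.19 (9.2e-02) with length and GC trends removed. HIF targets for the double mutant minus TIN were called at −0.24 (2.5e-02) without a filter, and without single libraries ranged from −0.33 (without double-mutant hypoxia A, 1.8e-02) to −0.16 (without TIN normoxia A). For TIN minus GLAD their list test changed direction at a median of 0.10 with a pseudocount of 0.1 CPM, 0.11 without TIN normoxia B and 0.06 without TIN hypoxia B, without a call. The median ranged from 0.03 (without TIN normoxia A) to 0.12 (without GLAD normoxia A) without single libraries, and was 0.02 with length and GC trends removed.

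Some genes without a stable call against wild type changed sign. For GLAD, Gapdh ranged from −0.17 to 0.02, Pdk1 from −0.15 to 0.10 and Pgk1 from −0.04 to 0.10 without wild-type library A or B. For TIN, Bnip3 ranged from −0.07 to 0.14 without TIN normoxia B or A, Pdk1 from −0.17 to 0.10 without wild-type B or A, and Vegfa from −0.02 to 0.08 without wild-type B or A. With CPM not scaled further Pdk1 stood at 0.02 for GLAD and 0.02 for TIN.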

Other observations

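The tests of DNA copy number, of the TIN substitution, of the cell line and of splits that keep libraries A and B together were chosen after the result was seen, and the other tests before.

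Single marker genes of other cell types also moved in these fibroblasts. The neural stem cell factor Sox2 was higher than in the wild type by 1.29 ± 0.15 in GLAD (adjusted p = 1.9e-06), 3.48 ± 0.15 in TIN (1.4e-12) and 1.89 ± 0.15 in the double mutant (1.3e-08). The lipid droplet gene Plin4 was higher by 2.26 ± 0.10, 2.31 ± 0.10 and 1.68 ± 0.10, and fell in hypoxia by 1.30 ± 0.06 on average (2.9e-12). The lysosomal gene Cd68, known from macrophages, rose in hypoxia by 1.36 ± 0.13 in GLAD, 2.44 ± 0.13 in TIN and 1.90 ± 0.13 in the double mutant, while the medians of the 4 measured myeloid markers were 0.03, 0.62 and −0.17. The contractile genes Tagln and Myl9 were lower in TIN than in GLAD in normoxia, by 2.10 ± 0.12 and 3.96 ± 0.15, and Tagln stood at −2.03 ± 0.12 in the double mutant against GLAD.

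Single keratin genes also differed. Krt15 was higher in TIN than in GLAD by 2.17 ± 0.19 in normoxia and 1.77 ± 0.19 in hypoxia, and Krt19 by 1.52 ± 0.22 and 0.84 ± 0.22. In the double mutant Krt19 was lower than in GLAD by 1.92 ± 0.22 in normoxia, and Krt18 was higher by 1.39 ± 0.23.

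The mean hypoxia effect was set against other splits of the 12 mutant libraries into 6 and 6. In a limma fit with genotype and split, the real split gave 8639 genes and the highest of 99 other splits drawn at random gave 2495. The split with 2495 separated oxygen in the double mutant alone. Most others parted libraries A and B, possible technical repeats, and gave 0 genes. Of 10 splits keeping A and B together the real one gave the most genes and the next, with 2812, separated oxygen in TIN alone. Chance cannot be judged from these splits.

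The chromosome-wide shifts between the mutants may reflect DNA copy-number differences between their cells, as a hypothesis. The chromosome medians of TIN against GLAD ranked alike in normoxia and hypoxia, at a Spearman rho of 0.94, which such differences need. Medians of 50 neighbouring genes spread 2.65 times as widely as in random gene orders, above the widest of 1000 orders, which argues against chance clustering. The windows also spread more than random for the hypoxia effect within 1 mutant, at ratios of 1.34 to 1.65. In the differences of the hypoxia effect, where a fixed copy-number difference cancels, the ratios were 2.04 for TIN minus GLAD and 1.88 for the double mutant minus TIN. The source of that part was not tested. A DNA measurement of the 3 lines would decide between copy number and a regulated change.

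The low p53 targets and high telomere genes of TIN against GLAD in normoxia went with its low interferon genes; against wild type the p53 and telomere calls ended with an estimated correlation (1.2e-01 and 1.4e-01). Cdkn1a in TIN against GLAD stood at −2.87 in normoxia and −0.12 (2.1e-01) in hypoxia, where it was higher in the double mutant than in TIN by 0.91. These features could belong to 1 line or culture, as the interferon genes of the double mutant against wild type at 0.04 and of TIN against GLAD in hypoxia at −2.28 leave open. A second, independently made TIN line would separate line from substitution. For glycolysis, the double mutant responded less to hypoxia than GLAD from a higher normoxic level. The estimated correlation left this list at −0.47 without a call, and lactate or oxygen consumption was not measured here.

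The wild-type libraries were used at normoxia alone, so whether the NMR protein itself alters the hypoxia response was not tested. Terf1 fell in hypoxia in all 3 mutants, but reads of the mouse gene and of the introduced sequence were not separated. Alignment of the reads to the NMR sequence would show which transcript fell.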
